A study of Homo sapiens with 6 samples.

How the data were processed

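Total RNA of HT29, a human colorectal cancer cell line, was sequenced in 6 libraries, 3 from cells cocultured with Fusobacterium nucleatum and 3 from a medium control. Groups and replicate numbers were taken from the sample titles and treatment labels. The RNA was extracted with Trizol and the libraries followed a standard Illumina protocol, per the labels. The deposited files hold whole-number read counts per Ensembl gene, 1 file per library, with 60483 genes each and no normalization. Per the submitters' processing notes, the tools named were HISAT2 version 2.1.0, TopHat and featureCounts and the genome build was hg38, also called GRCh38. The role of each aligner, the annotation release, strandedness, read length and pairing are not given in the sources used here. Without a stated strand, reads of overlapping and antisense genes cannot be told apart, and how reads shared by near-identical copies were counted is also not given in the sources used here.

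Ensembl gene identifiers were matched to gene symbols for 56321 genes and to GENCODE release 29 on GRCh38 for 56753 genes, which gave the biotype, chromosome, start and end. All 37 mitochondrially encoded genes had a count of 0 in every library. They were among 27675 of the 60483 genes with a count of 0 in all 6 libraries.

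The counts as deposited were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group as factor and a minimum count of 10, which left 15284 genes, and libraries were scaled by trimmed mean of M values (TMM). A quasi-likelihood model with robust estimation was fitted to the group alone, and each gene was tested two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic, and intervals are 95% intervals of the same model. CPM values, a gene's counts relative to the TMM-scaled library total, were computed here from the deposited counts. For the later checks on cancer panel genes and on leukocyte, fibroblast or endothelial RNA, CPM were instead taken on plain library totals. The 42 gene lists were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives below except where stated. The 38 lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over lists. Camera was repeated with an estimated correlation, and fry was run on the same lists. With an estimated correlation camera has only the few degrees of freedom that 6 libraries leave, so few lists can pass it.

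Named genes were METTL3, METTL14, WTAP, FTO, ALKBH5, YTHDF2, YAP1, FOXD3 and KIF26B, where tested. To these were added the 12 largest rises and 12 largest falls among protein-coding genes past the threshold with a symbol, a mean of at least 5 CPM, and all 3 libraries of one group beyond all 3 of the other. For each list, up to 4 members with the smallest adjusted p among those past the threshold were added. Where fewer than 2 passed, the 2 members with the highest mean CPM were taken. Some genes that the rule takes are not reported here, and 3 members of the cholesterol list are not drawn. Genes named outside the rule are said to have been chosen after their values were seen.

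Alternatives were RLE size factors, upper-quartile scaling, library totals only, no filter on low counts, a stricter filter (CPM above 1 in all 3 libraries of a group), DESeq2 1.42.0, limma-voom, the replicate number as a block, protein-coding genes only, a test against a 1.2-fold change (glmTreat), and leaving out each library in turn. Per-library offsets for GC content and exonic length (mgcv 1.9.3, smooth terms of basis size 8) and the removal of 314 genes commonly covered by cancer sequencing panels were added after the data were seen.

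The procedure was tested on simulated counts for this comparison, with 15160 genes tested, 200 genes changed, 50 at each fold size, and 40 more raised by 0.4 log2. Changes of 1.25, 1.5, 2 and 4 fold were called with the right sign for 26%, 74%, 92% and 100% of genes, and 6.47% of calls were unchanged genes. Far fewer genes were changed than the 4439 called in the data, so the adjustment cut at a smaller p. These shares therefore do not measure the sensitivity of the comparison itself. Total counts lay between 20341984 and 23900376 per library, and 3 counts, the limit that a count of 0 allows, corresponded to 0.125 to 0.151 CPM. Floors cover counting error only, while the 95% intervals of fold changes reflect the spread between these libraries. The genes left out by the filter held 0.108% to 0.170% of each library's counts.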

Results

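HT29, an epithelial line from a human colorectal adenocarcinoma, was sequenced after coculture with Fusobacterium nucleatum and in a group labelled medium control. Fusobacterium nucleatum is an anaerobic bacterium of the mouth that is also found in colorectal tumours. The series title places this comparison in the study of m6A, the methylation of adenosine within messenger RNA. Each group held 3 libraries of cells between passages 16 and 19. Total counts were 23178152, 22007764 and 20934011 in the coculture libraries and 20728323, 20341984 and 23900376 in the control libraries. Log2 CPM correlated between libraries of the same group at 0.991 to 0.993 (Pearson's r across genes, which are not independent replicates) and between groups at 0.981 to 0.986. The first principal component, with 57.1% of the variance, separated the groups. All pairs of libraries differed by more than sampling noise, with a chi-square per degree of freedom of at least 6.30. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

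Interferon-stimulated genes rose and cholesterol synthesis genes fell in coculture, each across nearly the whole list. IFI27, a mitochondrial protein induced by interferon, went from 64.7 ± 5.85 CPM in control to 230.3 ± 15.2 CPM in coculture (SD, n = 3 each), and INSIG1, a sterol-regulated brake on cholesterol synthesis, from 67.6 ± 19.2 to 17.2 ± 0.700 CPM. Of 15284 genes tested, 2083 were higher and 2356 lower in coculture (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and of these 99 were higher and 355 lower by at least 2-fold. Of the 355 falls 46, and of the 99 rises 1, were among 314 genes commonly covered by cancer sequencing panels, a set written after the values were seen and called panel genes here. Of these 314 genes, 66 had a mean under 1 CPM on plain library totals. Of the 66, 54 (81.8%) were higher in every control library than in every coculture library, against 11.3% of 5562 other coding genes under 1 CPM. The comparison is no independent test, because the set was written after this pattern was seen. The other genes also include some counted in a single library only, which cannot separate in this way. The split of calls depended on scaling: 46.9% were higher here, 30.9% with library totals only (1385 higher, 3092 lower) and 60.7% with GC and length offsets (3587 higher, 2319 lower), an alternative chosen after seeing the data. Without medium control replicate 2, 1293 genes were higher. The groups did not overlap for 6599 genes (43.2%), where chance gives 10%. Protein-coding genes made up 1960 of the rises and 2041 of the falls.

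Among protein-coding genes with a mean of at least 5 CPM, the largest rises were those of LAMP3, IL32 and DHRS2. LAMP3, a lysosome-associated membrane protein, rose from 1.59 CPM in control (log2 fold change 2.89, SE 0.20, edgeR adjusted p = 1.3e-08). The cytokine IL32 rose from 1.38 CPM (2.80, SE 0.17, adjusted p = 2.9e-09). The dehydrogenase DHRS2 rose by 2.47 (SE 0.13, adjusted p = 4.7e-10). IFI6, IFI27, OAS2, OAS3, MX2 and MX1, all interferon-stimulated, followed with rises between 1.45 and 2.18. The inositol kinase ITPKA rose by 1.70, the chaperone CLGN by 1.56 and the protease inhibitor SLPI by 1.49. Among the largest falls were those of INSIG1 (-1.97, SE 0.17, adjusted p = 2.8e-06), ACAT2, a cytosolic enzyme of acetyl-CoA metabolism (-1.94, SE 0.14, adjusted p = 6.5e-08), and CLDN2, a claudin that forms cation pores in tight junctions (-1.93, SE 0.15, adjusted p = 1.3e-06). KIF3C fell by 1.72 on the log2 scale, the proteoglycan gene CSPG4 by 1.59, LOXL1 by 1.49, SLC2A6 by 1.46, STARD4 by 1.41, LINC03040, which release 29 lists as protein-coding, by 1.40 and PTPRO by 1.39. S100A4, a calcium-binding protein associated with cell motility, went from 211.9 ± 16.7 to 75.1 ± 6.14 CPM (SD, n = 3). The calls of these genes held in each alternative fit to which they were put.

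The genes that write, remove and read m6A went in both directions. METTL3, the catalytic subunit of the m6A methyltransferase (ENSG00000165819.10, GRCh38 chromosome 14, 21498133 to 21511375), was at 32.6 ± 0.880 CPM in coculture and 36.6 ± 2.44 CPM in control (SD, n = 3). Its log2 fold change of -0.17 (95% interval -0.36 to 0.03) did not pass the edgeR test (adjusted p = 0.19), although every control library lay above every coculture library. Its partner METTL14 (-0.20, adjusted p = 0.26) and the adaptor WTAP (-0.08, adjusted p = 0.52) did not pass either. Without coculture replicate 1, METTL14 stood at -0.34 and passed. The demethylase ALKBH5 (ENSG00000091542.8, chromosome 17, 18183078 to 18209954) rose from 52.4 ± 4.39 to 73.1 ± 7.30 CPM (log2 fold change 0.48, SE 0.09, adjusted p = 9.5e-04). FTO, the other demethylase, was at 0.19 (adjusted p = 0.18) and passed only with GC and length offsets (0.33). The reader YTHDF2 (ENSG00000198492.13, chromosome 1, 28736621 to 28769775) rose by 0.24 (SE 0.08, adjusted p = 0.025), a call lost with library totals only (0.17) and without medium control replicate 2 (0.23). Of 12 tested writer genes, 3 rose and 2 fell, the same numbers when adjusted over the list alone (camera adjusted p = 0.97): METTL16 rose by 0.60 and RBM15 by 0.43, and RBM15B fell by 0.68 on the log2 scale. Of 15 erasers and readers, 4 rose and 1 fell, again the same when adjusted over the list alone (camera adjusted p = 0.35), with YTHDF1 up by 0.48.

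**Figure D1:**
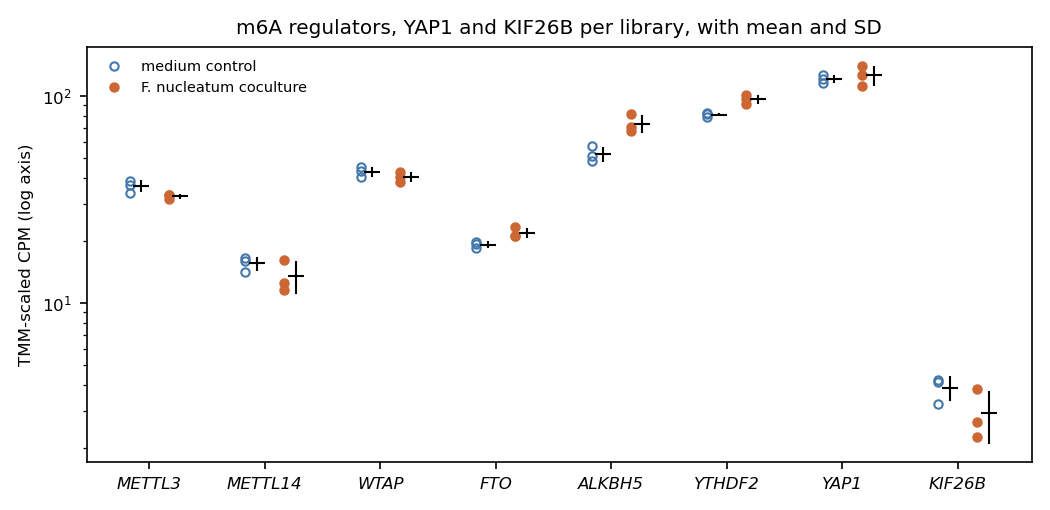
TMM-scaled CPM (log axis) of METTL3, METTL14, WTAP, FTO, ALKBH5, YTHDF2, YAP1 and KIF26B in each library of medium control (open) and coculture (filled), with mean and SD of 3 libraries. ALKBH5 and YTHDF2 were higher in coculture, and the other genes did not pass the test.

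YAP1, the transcriptional coactivator restrained by the Hippo kinases, was at 125.5 ± 13.98 CPM in coculture and 121.1 ± 5.31 CPM in control (log2 fold change 0.05, SE 0.09, adjusted p = 0.69), and its sign turned with library totals only (-0.022) and without coculture replicate 1 (-0.006). Of 18 Hippo pathway genes, 3 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.97). TEAD2, a partner of YAP1, fell by 0.61 on the log2 scale, and the tumour suppressor NF2 rose by 0.37. Among 18 YAP and TAZ targets, 1 rose (MYOF, 0.55) and 3 fell (ARHGEF17, -0.46, ASAP1, -0.41, and NT5E, -0.37), or 2 and 4 when adjusted over the list alone (camera adjusted p = 0.69). The kinesin KIF26B (log2 fold change -0.41, SE 0.20, adjusted p = 0.14) passed without coculture replicate 2 (-0.65). FOXD3 had a count of 0 in all 6 libraries.

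Of 33 tested interferon-stimulated genes, 28 rose and 0 fell, or 29 and 0 when adjusted over the list alone, with a median log2 fold change of 1.06. The list was higher by camera (adjusted p = 4.1e-18) and not past the threshold with an estimated correlation (adjusted p = 0.27). The 2'-5'-oligoadenylate synthetases, which sense double-stranded RNA, rose together: OAS1 by 1.27, OAS2 by 1.82 and OAS3 by 1.54, the last from 74.9 ± 6.92 to 217.2 ± 7.69 CPM (SD, n = 3). The NF-kB and inflammatory list moved both ways, with 8 of 23 genes higher and 5 lower, the same numbers when adjusted over the list alone (camera adjusted p = 0.35). BIRC3, an inhibitor of apoptosis, rose by 0.996, and TNFAIP2 fell by 0.35 and TRAF1 by 0.51 on the log2 scale. Among 17 innate sensors and antimicrobial genes, 2 rose and 1 fell, as when adjusted over the list alone (camera adjusted p = 0.97). LCN2, an iron-sequestering antimicrobial protein, rose by 0.70 and IL18 by 0.64, while TLR4, the receptor of bacterial lipopolysaccharide, fell by 1.001 on the log2 scale at 1.97 against 3.96 CPM.

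**Figure D2:**
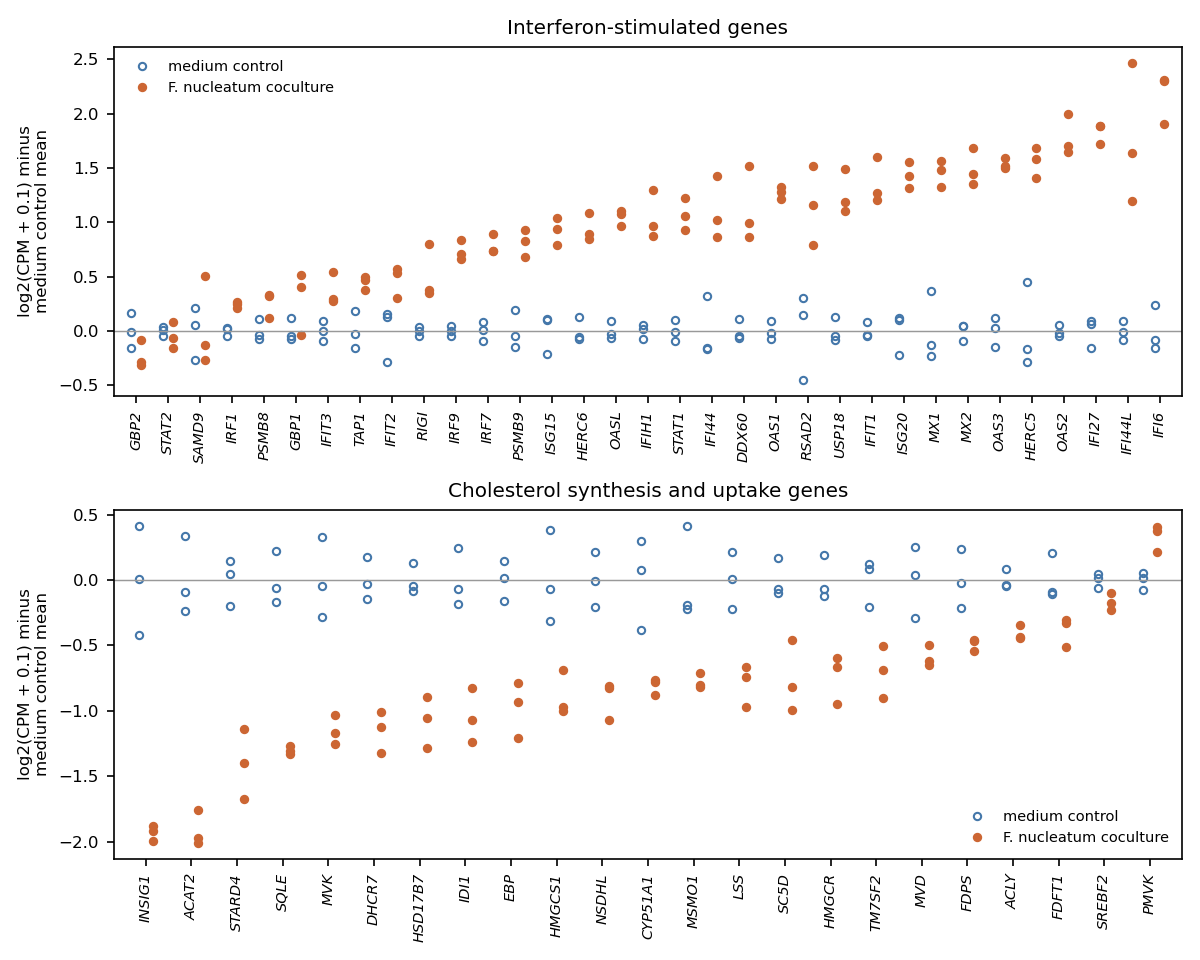
Per-library log2(CPM + 0.1) minus the mean of the 3 medium control libraries for the 33 interferon-stimulated genes (top) and 23 of the 26 cholesterol synthesis and uptake genes (bottom), open points for control and filled points for coculture. Of the genes drawn, 28 interferon-stimulated genes were higher and 21 cholesterol genes lower in coculture.

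Of 26 cholesterol synthesis and uptake genes, 24 fell and 1 rose, or 25 and 1 when adjusted over the list alone, with a median log2 fold change of -0.91. The list was lower by camera (adjusted p = 2.5e-12), and not past the threshold with an estimated correlation (adjusted p = 0.69). SQLE, a rate-limiting epoxidase of the pathway, went from 230.5 ± 33.2 to 92.9 ± 2.03 CPM (SD, n = 3), a fall of -1.31 on the log2 scale, beside the falls of INSIG1, ACAT2 and STARD4. Among 21 fatty acid and lipid genes, 10 fell and 1 rose, or 11 and 2 when adjusted over the list alone (camera adjusted p = 0.037, and adjusted p = 0.69 with an estimated correlation). The desaturase SCD went from 978.9 ± 45.4 to 486.0 ± 7.17 CPM (SD, n = 3), and ACSL1 fell by 0.98, FASN by 0.61 and ACACA by 0.49 on the log2 scale. Without medium control replicate 3 the fatty acid list had a median of -0.36 and an adjusted camera p of 0.056, with 0.0027 to 0.085 over all its alternatives.

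Ribosomal protein genes were modestly higher, with 33 of 75 rising and 0 falling, or 43 and 0 when adjusted over the list alone, and a median log2 fold change of 0.23 (camera adjusted p = 9.3e-11, and adjusted p = 0.83 with an estimated correlation). The median stayed between 0.15 and 0.29 under all alternatives, but the number of rises did not: it was 50 without coculture replicate 1 or medium control replicate 3, 21 without coculture replicate 2, 20 without medium control replicate 1, 17 without medium control replicate 2, 54 with GC and length offsets and 4 in the test against a 1.2-fold change. RPL10 rose by 0.52, RPL27 by 0.49, RPSA by 0.48 and RPS12 by 0.46, values that remain uncertain because these genes have many near-identical pseudogene copies. Of 46 nuclear genes of oxidative phosphorylation, 15 rose and 4 fell, or 20 and 4 when adjusted over the list alone (median 0.20, camera adjusted p = 5.6e-04, and adjusted p = 0.83 with an estimated correlation). In that list 7 genes rose and 3 fell without medium control replicate 2, 8 and 5 with library totals only, 27 and 3 with GC and length offsets, and 3 and 0 in the test against a 1.2-fold change. UQCRQ and SDHD rose by 0.53 each and NDUFA9 by 0.51, and ATP5F1C fell by 0.38 on the log2 scale. All 37 mitochondrially encoded genes, 13 of them listed, were at 0 counts. Among 33 ribosome biogenesis genes, 6 rose and 5 fell, or 7 and 5 when adjusted over the list alone (camera adjusted p = 0.13). RRP9 rose by 0.97, RRP12 by 0.54 and PES1 by 0.37.

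The integrated stress and unfolded protein response list had 11 of 34 genes higher and 3 lower, the same when adjusted over the list alone (median 0.12, camera adjusted p = 0.041, and adjusted p = 0.83 with an estimated correlation). DNAJB9 and DNAJC3, chaperone cofactors of the endoplasmic reticulum, rose by 0.98 and 0.76, and SHMT2, a mitochondrial enzyme of serine metabolism, by 0.60. The call of this list was lost with a stricter filter, with the replicate number as a block, with protein-coding genes only, with GC and length offsets and without the panel genes. It was also lost without medium control replicate 3, where the median was 0.08, with 8 genes higher and 5 lower. With library totals only the median was 0.04, with 7 higher and 6 lower, and without medium control replicate 1 it was 0.225, with 14 and 3. The counts were 7 and 0 in the test against a 1.2-fold change. Over all its alternatives the adjusted camera p ranged from 0.0036 to 0.22.

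Most DNA replication genes that passed were lower, and the list itself was not called. Of 40 genes of the G1/S transition and DNA replication, 13 fell and 2 rose, or 15 and 2 when adjusted over the list alone (median -0.22, camera adjusted p = 0.085). The replicative helicase subunits MCM6, MCM3 and MCM4 fell by 0.85, 0.63 and 0.57, and the ligase LIG1 by 0.77 on the log2 scale. The list passed without coculture replicate 2 (median -0.25) or 3 (-0.26), without medium control replicate 1 (-0.30) or 2 (-0.25), with limma-voom and with GC and length offsets. Of 38 G2/M genes, 6 rose and 6 fell, or 7 and 9 when adjusted over the list alone (camera adjusted p = 0.89). CDC20, an activator of the anaphase-promoting complex, rose by 0.43. Among 30 DNA repair genes, 10 fell and 1 rose, or 12 and 1 when adjusted over the list alone (camera adjusted p = 0.12). BLM, BRIP1 and BRCA2 fell by 0.69, 0.75 and 0.64 on the log2 scale, all of them panel genes. Replication-dependent histone genes had 3 of 23 lower and 0 higher, and 0 when adjusted over the list alone (camera adjusted p = 0.36). Of 26 kinesin genes, 7 fell and 2 rose, or 9 and 2 when adjusted over the list alone (camera adjusted p = 0.35), among them KIF15 (-0.78), KIF12 (-0.75) and KIF9 (0.64).

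Adhesion and signalling lists held changes in both directions. Of 26 tight and adherens junction genes, 8 rose and 5 fell, or 9 and 6 when adjusted over the list alone (camera adjusted p = 0.57): CLDN1 and MARVELD2 rose by 0.50 and 0.51, and NECTIN1 fell by 0.81 on the log2 scale. Among 18 genes of epithelial-mesenchymal transition and migration, 3 rose and 3 fell, as when adjusted over the list alone (camera adjusted p = 0.97), with TGFBI at 0.49 and the adhesion receptor CD44 at -0.36. Of 21 Wnt targets, 3 rose and 6 fell, or 4 and 6 when adjusted over the list alone (camera adjusted p = 0.75), including the Wnt antagonist DKK1 (-0.90) and TCF7 (-0.40). The 17 TGF-beta targets had 3 higher and 4 lower, also when adjusted over the list alone (camera adjusted p = 0.89). ID2 fell by 0.99, TGFB1 by 0.82 and ID1 by 0.65 on the log2 scale, and the cell cycle inhibitor CDKN1A rose by 1.09. Of 29 immediate early genes, 5 rose and 9 fell, or 6 and 9 when adjusted over the list alone (camera adjusted p = 0.77), with EGR1 at -1.14, NR4A1 at -0.68, BTG2 at -0.64 and SPRY4 at -0.60. Of 12 lectin, adhesion and bacterial receptor genes, 2 rose and 3 fell, or 3 and 3 when adjusted over the list alone (camera adjusted p = 0.97): ANXA1 rose by 0.55 and GALNT12 fell by 0.72 on the log2 scale, and CEACAM6 rose by 0.55, with reads that may be shared among its close relatives.

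Further stress and metabolic lists were not called. Of 27 NRF2 and oxidative stress genes, 2 rose and 6 fell, as when adjusted over the list alone (camera adjusted p = 0.51), among them AKR1B10 (-1.02), GPX2 (-0.59) and FTH1 (0.42). Of 21 heat shock genes, 2 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.75). HSPB1 fell by 0.90 and HSPH1 by 0.51 on the log2 scale, while HSPA6, whose reads may be shared with near-identical relatives, stood at 2.91 against 0.134 CPM (log2 fold change 4.37, SE 0.34, adjusted p = 5.6e-08). Among 6 metallothionein and zinc genes, 0 rose and 2 fell, or 0 and 4 when adjusted over the list alone (camera adjusted p = 0.17), with MT1E at -0.61 and uncertain because of its close paralogs. Of 24 hypoxia genes, 3 rose and 4 fell, or 4 and 4 when adjusted over the list alone (camera adjusted p = 0.89), including CA12 (-0.97), NDRG1 (-0.66) and ERO1A (0.44). Of 22 glycolysis genes, 3 rose and 8 fell, as when adjusted over the list alone (camera adjusted p = 0.35), including PFKFB4 (-1.37), ALDOC (-1.09) and ENO2 (-0.68). The iron and ferroptosis list had 4 of 16 higher and 4 lower, also when adjusted over the list alone (camera adjusted p = 0.77), with AIFM2 at 0.52, TFRC, the transferrin receptor, at -0.50 and the iron exporter SLC40A1 at -0.49.

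Of 33 autophagy and lysosome genes, 7 rose and 3 fell, as when adjusted over the list alone (camera adjusted p = 0.23), with the autophagy receptor SQSTM1 at 0.37 and MAP1LC3B at 0.42. The 23 p53 targets had 2 higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.89). FAS, a death receptor and a panel gene, went from 2.87 to 1.02 CPM (-1.48). Among 27 apoptosis genes, 5 rose and 4 fell, as when adjusted over the list alone (camera adjusted p = 0.36), with BMF at 0.69, BID at -0.39 and BCL2, also a panel gene, at 0.316 against 1.56 CPM. Of 28 genes of intestinal differentiation and mucins, 9 rose and 8 fell, or 10 and 9 when adjusted over the list alone (camera adjusted p = 0.89), with AGR2 at 0.64, LGALS4 at 0.59 and MUC2 at -0.89. Among 15 stemness genes, 1 rose (KLF4, 0.45) and 3 fell, as when adjusted over the list alone (camera adjusted p = 0.25), with CD24 at -0.58. Of 25 genes of nonsense-mediated decay and RNA processing, 4 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.97), with SON at 0.33. Of 15 long noncoding RNAs, listed as nuclear-retained although several are spliced host genes of small nucleolar RNAs, 6 rose and 1 fell, or 7 and 1 when adjusted over the list alone (camera adjusted p = 0.058). All 6 that rose are such host genes, with ZFAS1 and SNHG15 at 0.61 each and GAS5 at 0.49. That list passed in 7 of 16 alternatives: library totals only, no filter, limma-voom, and without coculture replicate 2 (median 0.24) or 3 (0.20) or medium control replicate 1 (0.23) or 2 (0.18).

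**Figure D3:**
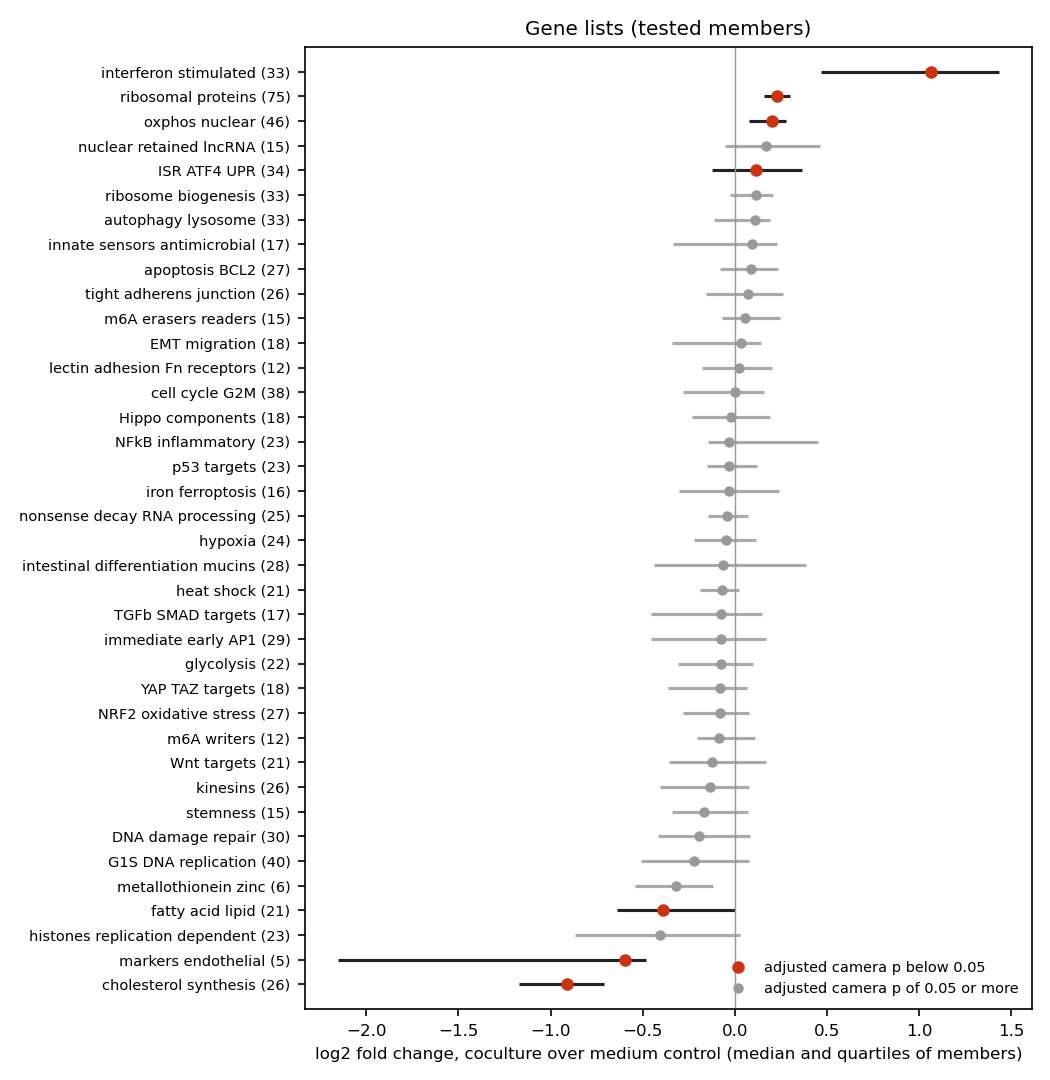
Median (point) and quartiles (line) of the log2 fold change, coculture over medium control, of the tested members of the 38 lists with at least 5 of them. Red points mark the 7 lists with an adjusted camera p under 0.05, none of which passed with an estimated correlation.

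Of the 38 lists, 4 were called higher and 3 lower by camera, and 0 with an estimated correlation, where 1 list had an unadjusted p under 0.05. That count of 0 does not show that correlation alone undoes the calls, because 6 libraries leave this version few degrees of freedom. Fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes, called 8: the interferon-stimulated, cholesterol, fatty acid and endothelial lists, and also the metallothionein, DNA repair, autophagy and stemness lists. It did not call the ribosomal protein (fry adjusted p = 0.094), oxidative phosphorylation (adjusted p = 0.15) and stress response lists (adjusted p = 0.12). With no filter on low counts, where the comparison includes genes with almost no counts, the NF-kB (camera adjusted p = 0.030), metallothionein (adjusted p = 0.025), histone (adjusted p = 0.029), ribosome biogenesis (adjusted p = 0.014) and autophagy (adjusted p = 0.042) lists passed, ribosome biogenesis also without coculture replicate 2 (adjusted p = 0.031). For 13 lists, all with an adjusted camera p of at least 0.35, the median, the mean and the camera direction differed in sign. They were the Hippo, NF-kB, innate sensor, epithelial-mesenchymal, junction, p53, heat shock, G2/M, intestinal, lectin, iron, apoptosis and RNA processing lists.

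Most listed markers of other cell types were too low to test, and several of those tested were lower in coculture. Of 5 tested endothelial markers, 3 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.041, and adjusted p = 0.69 with an estimated correlation). KDR went from 2.61 to 0.189 CPM and PECAM1 from 2.03 to 0.450 CPM, and ENG from 31.4 to 22.6 CPM. The call of the endothelial list was lost with library totals only, with the replicate number as a block and without coculture replicate 1 (median -0.41). Its adjusted camera p was 0.0084 to 0.085 over its alternatives, and too few members were left to test it without the panel genes. Of 4 fibroblast markers, 3 fell and 0 rose, as when adjusted over the list alone, among them PDGFRA (1.60 to 0.169 CPM) and PDGFRB (2.01 to 0.330 CPM). With fewer than 5 tested members the fibroblast list was not put to camera here, but it was called with no filter, without coculture replicate 1, 2 or 3 and without medium control replicate 1 or 3. Of 4 leukocyte markers, 1 fell and 0 rose, also when adjusted over the list alone. The marker that fell was CSF1R, a panel gene named after its values were seen, with 5, 10 and 12 counts in coculture and 23, 30 and 19 in control. LYZ, which was abundant in all libraries, stood at -0.19 (adjusted p = 0.087) and ITGAM at -0.45 (adjusted p = 0.16). LYZ passed the edgeR test with library totals only (-0.262, adjusted p = 0.012) and with the replicate number as a block (-0.185, adjusted p = 0.021). The only neuroendocrine marker tested, SYP, was at -0.34 (adjusted p = 0.28), so that 0 passed in either adjustment. KDR, PDGFRA, PDGFRB, FAS, BCL2, BLM, BRIP1, BRCA2, NF2, CDKN1A, SDHD and HSP90AA1 were panel genes.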

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

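Per-library offsets for GC content and length and the removal of panel genes were chosen only after the results were seen. The 2083 genes higher in coculture became 1385 with library totals only, 3587 with GC and length offsets and 597 with a test against a 1.2-fold change, which also left 905 of the 2356 lower genes. That test asks for a larger change by construction. With library totals only, fold changes shifted by a median of -0.074 on the log2 scale, which moves genes from the higher to the lower side. With GC and length offsets the median shift was 0.055, and whether that shift alone raised the number of calls was not tested. Leaving out each library in turn gave 1293 to 2343 higher and 1583 to 2470 lower genes, with 93 to 120 higher and 299 to 407 lower by at least 2-fold. The lowest count of higher genes, 1293, came without medium control replicate 2. Between 63.8% and 87.7% of the 4439 called genes were kept when a library was left out, 89% with DESeq2, 97.8% with limma-voom and 96.4% without panel genes. The 7 lists called by camera became 14 with no filter on low counts, 0 with an estimated correlation, and 6 to 11 when a library was left out, with 11 without coculture replicate 2. With the replicate number as a block (replicate block), 5521 genes were called, 99.9% of the main calls were kept, and 4 lists were called, with adjusted p of 0.085 for the fatty acid, 0.090 for the stress response and 0.085 for the endothelial list, and 56 ribosomal protein and 24 oxidative phosphorylation genes rose. Deviations from the group means correlated at 0.157, -0.031 and 0.075 between libraries of the same number, so the numbers were not taken to pair the libraries. YAP1, not called in any fit, turned to -0.022 with library totals only and lay between -0.006 (without coculture replicate 1) and 0.134 when a library was left out. Over 168 named genes, 2755 of 2836 values kept their direction and side of the threshold, 74 were weaker, 5 stronger and 2 reversed, with 0 adjusted p-values missing in DESeq2. Over 38 lists, 614 of 644 values kept both, 11 were weaker, 19 stronger and 0 reversed. Depth limited the genes near 0.125 to 0.151 CPM, the level of 3 counts.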

Other observations

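The MHC class I, small nucleolar RNA host, translation and LXR target lists and the tests of explanations were chosen only after the results were seen, and the bounds for other splits were also written then. Of 20 tested genes of antigen presentation by MHC class I, 9 rose, 1 fell and 10 did not pass (median log2 fold change 0.27, camera p = 4.3e-04, and p = 0.10 with an estimated correlation). B2M, the light chain of the complex, rose by 0.35. Several members share near-identical sequence, so their values remain uncertain. Host genes of small nucleolar RNAs rose in 13 of 24 cases and fell in 2 (median 0.33, camera p = 1.8e-04, and p = 0.10 with an estimated correlation), led by SNHG32 at 1.43, and 6 of the 13 also belong to the long noncoding RNA list fixed beforehand. Among 24 translation genes with a 5' terminal oligopyrimidine tract other than ribosomal proteins, 9 rose and 0 fell (median 0.17, camera p = 4.7e-04, and p = 0.19 with an estimated correlation).

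The genes of this paragraph were chosen after their values were seen. The glucose-responsive arrestins TXNIP and ARRDC4 rose by 0.98 and 1.03, TXNIP from 504.5 to 995.2 CPM. Of 21 interferon ligand genes, 18 had any count. IFNE had the highest total, with 41, 29 and 21 counts in coculture and 62, 58 and 61 in control. IFNL1 had 16 and IFNB1 8 counts over all 6 libraries. The others with any count had at most 3 in total, most of them only in medium control replicate 1. Medium control replicate 1 had 1862 genes counted in no other library, none above 7 counts, against 546 to 896 such genes in each other library. Of the 1862, 883 were protein-coding, against 90 to 154 in each other library.

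Interferon-stimulated genes were higher in coculture (28 of 33, median log2 fold change 1.06). With offsets for GC content and exonic length the median was 1.10, which speaks against those trends as the whole cause. On plain library totals, the summed level of 17 leukocyte markers, without LYZ, was 3.79 CPM in coculture and 5.62 CPM in control. That difference of -1.83 CPM, against a rise of 784.9 CPM over the interferon-stimulated genes, speaks against leukocyte RNA. A candidate explanation is a response of the cells to the coculture. Differences in medium or cell density between the groups were not tested for these genes.

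Cholesterol synthesis genes were lower in coculture (24 of 26, median -0.91), and with GC and length offsets the median was -0.88, which speaks against those trends as the whole cause. A higher sterol load of the cocultured cells may lower these genes, and would raise targets of the sterol sensor LXR. Of 7 tested LXR targets, 2 rose (ABCG1 by 0.67) and 2 fell (ABCA1, -0.50), with a median of 0.22, so this explanation cannot be told apart from others, because members went both ways. A difference in medium or cell density between the groups was not tested.

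Panel genes near the counting floor were higher in control in 54 of 66 cases, a share that tests nothing by itself because the set was written after the pattern was seen. A candidate explanation is a trace of reads from a cancer panel DNA library in the control libraries. CPM in this paragraph are on plain library totals. Across these genes the excess in control grew with coding length (Spearman's rho 0.669, against 0.161 in other coding genes under 1 CPM, genes not being independent replicates). That trend does not decide, because the set was written after the excess was seen and added RNA reads would also grow with length. The other genes had little excess to compare (median 0.0162 CPM per kb). The median excess of the panel genes was 0.244 CPM per kb of coding sequence, which for BRCA2 comes to 2.54 of a difference of 6.95 CPM on library totals. For RNA of fibroblasts or endothelial cells, 6 genes abundant in such cells had a summed excess in control of 1.03 CPM, below the 5.71 CPM of KDR, PDGFRA and PDGFRB. COL1A1, which was not in that sum, had an excess of 1.32 CPM, and with it the sum stays below 5.71 CPM. In the sum, VIM, VWF and CDH5 had 0.061, 0.0093 and -0.016 CPM, which argues against such RNA as the source of the 5.71 CPM. COL1A2, COL3A1 and SPARC, also in the sum, had 0.556, 0.201 and 0.219 CPM. The endothelial gene PECAM1, which was not in the sum and is no panel gene, had 1.64 CPM. The excess of PECAM1 and the collagen genes stays unexplained. A lowering of the panel genes by coculture stays open and was not tested.

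The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For each of the 4 counts of genes (2083 higher, 2356 lower, and 99 and 355 by at least 2-fold), 1 of the 10 splits, the real one, gave as many, and the highest other split gave 0 by edgeR, with 90 to 731 genes at an unadjusted p under 0.05 against 6123 in the real split. Every other split mixes both groups, so the difference between groups enters its spread. Its count of 0 is therefore no baseline for chance. For lists, 4 of 10 splits gave at least the 7 of the real one, and the highest other gave 8. The mixed splits also keep part of the group difference in their own comparison, so their list results are no baseline for chance either. The smallest camera p of the other splits was 1.0e-07 for the interferon-stimulated list (1.1e-19 in the real split), 1.5e-07 for the cholesterol list (1.3e-13) and 0.022 for the fatty acid list (0.0049). For the other 4 called lists another split gave a smaller p than the real one: 3.7e-20 against 7.3e-12 for ribosomal protein genes, 1.2e-10 against 5.9e-05 for oxidative phosphorylation, 7.5e-05 against 0.0075 for the stress response list and 0.00682 against 0.00704 for endothelial markers.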
